A study of Mus musculus with 67 samples.

How the data were processed

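The study provided 67 samples of mouse J1 ES cells: 52 RNA libraries, 12 chromatin immunoprecipitation libraries with peak lists and 3 control chromatin libraries, 1 per factor. Groups, densities, LIF, doses and times were taken from the sample labels, and 2 of the shCon libraries (replicate 2 at each density) carry no treatment in their labels and were kept in the shCon group named in their titles. Knockdown cells carried a constitutive lentiviral shRNA. The tagged factors of the chromatin libraries were induced with 100 (β-catenin), 50 (Tcf7l1) or 10 (Esrrb) ng/mL dox and recovered with streptavidin. RNA libraries were sequenced on NovaSeq (paired-end) or NextSeq (unpaired) instruments.

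Per the submitters' processing notes, RNA reads were quantified with kallisto 0.46.1, and chromatin reads were aligned to mm10 with Bowtie2 2.4.2 and peaks called with MACS2 2.2.7.1. The transcript index given to kallisto is not given in the sources used here. The deposited RNA tables hold, per the file headers, an estimated count, a TPM and an effective length for each of 119414 transcripts, of which 104187 had a count above 0 in any library. The deposited peak tables hold, per the file headers, a summit pileup (signal, in tags), a fold enrichment (a ratio of the summit over the local control background), and -log10 p and -log10 q values (neg log10 p) as the authors ran MACS2. Peaks were called by the authors for each library alone against 1 control library of the same factor at high density, at a q threshold of 0.05, with 1 tag kept per position. Filtered tags were 13.2, 19.6, 20.3 and 18.9 M for β-catenin (high density replicates 1 and 2, then low), 17.8, 20.5, 20.1 and 17.8 M for Tcf7l1 and 13.0, 20.0, 14.0 and 17.2 M for Esrrb.

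The comparisons, tests, thresholds, gene lists and rule for named genes were chosen before the data were examined, from the labels alone. That design used gene sums, which could not be made because transcript identifiers (ENSMUST) are not paired with genes in the tables used here. All RNA tests were therefore run per transcript. RNA gene lists, cell type markers, the genes of the knockdowns and inductions, and peaks near density-responsive genes are not analysed here for the same reason. The rule for named genes (the factor genes, a panel of Nanog, Klf4, Pou5f1, Sox2, Axin2, T and Fgf5, the genes with the largest changes, and up to 4 members per list) was applied to peaks for the factor genes, the panel and list members. For RNA, 2 transcripts that rose and 2 that fell are named, those with the smallest p in the density trend without LIF. For each gene the peak described is the one with the highest fold in replicate 1, a choice made after the data were examined.

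Estimated counts were rounded and analysed in R 4.3.3 with edgeR 4.0.16 (with data.table, version 1.17.8). Transcripts with at least 1 CPM in at least 2 libraries of a fit were kept, library factors were made by the trimmed mean of M values (TMM), and quasi-likelihood tests were adjusted by Benjamini-Hochberg at 0.05. The seeding series was fitted with an intercept and a slope on log2 density for each LIF condition (14 libraries), and LIF withdrawal with the density as a block. The knockdown (18 libraries), medium exchange (8) and inducible (12) experiments were fitted by group means, with contrasts of high against low density, treated against control within a density, and the difference of these between densities. The lines without dox were fitted with line as a covariate (6 libraries). Where a group has 1 library it is assumed to vary like the others of its fit.

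The 200 transcripts with the smallest p and a positive slope without LIF, and the 200 with a negative slope, formed the density-rising and density-falling sets, of which 194 to 200 were present in each other fit. They were tested with camera (limma 3.58.1, on voom values) with a preset correlation of 0.01 between transcripts, as designed, and with an estimated correlation. Adjustment covered the 28 tests of the 3 other experiments. The trend with LIF comes from the same fit as the trend that defined the sets but from other libraries, and its 2 tests are unadjusted. The level of a set is the mean log2 CPM (prior count 2) of its members in a library. Its relation to density with LIF was tested by all 5040 orders of the 7 libraries.

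Peaks were handled in Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1) with bedtools 2.31.1. A peak counted as found in both replicates when a peak of replicate 1 overlapped one of replicate 2 by at least 1 bp, and overlap between factors or densities used the same rule. Overlap by chance was estimated from 100 circular shifts of the peaks along each chromosome. The shifts do not keep peaks in accessible or mappable sequence. An overlap above them therefore cannot separate shared binding from a shared preference for accessible chromatin. Peaks were assigned to every protein-coding gene (21887 RefSeq spans of GRCm38.p6) within 10 kb of its span, with no use of strand or start site. For 23 gene lists (310 genes, 309 with coordinates, all but Zscan4a), the share with a peak was compared with all other protein-coding genes by two-sided Fisher's exact test, adjusted over 138 tests per distance, and with 10000 draws of genes matched on span in 20 classes.

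Depth was 6.81 to 49.2 M (1e6) estimated counts per RNA library, so 3 counts equal 0.0609 to 0.44 CPM. On negative binomial counts simulated with the mean and dispersion of each transcript in each fit, 94 of 100 transcripts changed by a log2 slope of 1 per doubling of density and 99 of 100 by 2 were called in the density trend. With log2 changes of 1 and 2, 29 and 75 of 100 were called for LIF withdrawal, 37 and 79 for shCon high against low density, 21 and 74 for β-catenin knockdown at high density, 0 and 41 for the lines without dox, 0 and 16 for β-catenin 4A and 0 and 0 for the medium exchange. At most 31 unchanged transcripts were called. Changes were planted only in transcripts with a mean CPM of at least 3 on the log2 scale. camera found the shifted set in all 7 simulated comparisons. Transcripts were drawn independently of each other there, so the preset correlation was not tested. For peaks, 5 of 5 overlap tests on made intervals gave the planted overlap.

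Alternatives chosen before the data were examined were DESeq2 1.42.0, RLE factors, counts scaled from TPM, no filter on low counts, at least 5 CPM, only the compared groups or only 1 LIF condition in the fit, the replicate number as a block, a slope on density in place of pairing, sets of 100 or 400, sets from another experiment, an estimated correlation, leaving out each replicate or density, a -log10 q of at least 5, reciprocal overlap of 50% of each peak, and lists of the same number of peaks. Added afterwards were each shCon replicate as the lone control, library totals without the 20 most abundant transcripts, set tests with a library left out or with only the compared groups, and the settings of the gene list tests for peaks.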

Results

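J1 mouse embryonic stem (ES) cells, an established pluripotent line, were seeded at different densities, and their transcripts and the chromatin occupancy of 3 factors were measured. Leukemia inhibitory factor (LIF), a cytokine that sustains the self-renewal of mouse ES cells in serum, was either present or withdrawn so that the cells differentiated. The RNA data comprised 52 libraries in 4 experiments. A seeding series held 14 libraries, 1 for each of 7 densities from 7800 to 500000 cells per mL with LIF and 1 for each without it, all after 96 h. A knockdown experiment held 18 libraries after 72 h without LIF, at high (190000 cells per cm2) or low (23000 cells per cm2) density. It had 3 libraries per density titled shCon, for a non-targeting shRNA, of which replicate 2 carries no treatment in its labels. For each of Ctnnb1, Tcf7l1 and Esrrb it had 2 libraries per density with an shRNA against that gene. Ctnnb1 encodes β-catenin, the effector of canonical Wnt signalling. Tcf7l1 is a largely repressive DNA-binding partner of β-catenin, and Esrrb an orphan nuclear receptor of the naive pluripotency network. A medium exchange experiment held 8 libraries in 4 groups of 2, from cells kept in their own medium or given, for 4 h, the medium of cells at the other density. Inducible lines gave 12 libraries: β-catenin 4A (a form known here only by that name), Yap1 (a coactivator of TEAD factors in Hippo signalling) or Esrrb under doxycycline (dox) control, with 1 library per density without dox and 2 with dox for 48 h at 1 density. High-density cells grew in 6-well and low-density cells in 12-well plates, so plate format went with density in these 3 experiments.

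RNA libraries held between 6.81 and 49.2 M (1e6) estimated counts (median 16.3 M), with 10.8 to 28.5 M in the knockdown experiment, 6.81 to 15.8 M in the medium exchange, 9.19 to 30.9 M in the inducible lines and 8.77 to 49.2 M in the seeding series. Replicates of 1 group differed by more than sampling noise in all 19 pairs (chi-square per degree of freedom of 13.2 to 83.5). The labels do not say that replicates came from separate cultures, so every p-value below measures only the spread between these samples, which may be technical. The expression tables give transcript identifiers without gene names, and the files used here do not pair them. RNA results are therefore given per transcript and for groups of transcripts, and the transcripts of the knocked-down and induced genes were not analysed here. Chromatin data comprised peak lists of 12 libraries of tagged, dox-induced β-catenin, Tcf7l1 or Esrrb, 2 per factor and density, made from 13.0 to 20.5 M tags each after filtering.

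The seeding series asked which transcripts follow density as ES cells exit self-renewal. Without LIF, 3303 transcripts rose and 2509 fell with density among 40415 tested (edgeR's quasi-likelihood test on the slope, Benjamini-Hochberg adjusted p under 0.05, 7 libraries per condition). ENSMUST00000087566.10 rose by 0.63 ± 0.03 (SE) on the log2 scale per doubling of density, from 35.3 CPM (counts scaled to the library total) at the sparsest to 496 CPM at the densest seeding (adjusted p = 2.88e-07), and ENSMUST00000018918.11 rose by 0.87 ± 0.04, from 1.69 to 56.5 CPM (adjusted p = 2.88e-07). ENSMUST00000028280.13 fell by 0.52 ± 0.03 per doubling, from 85.8 to 10.6 CPM (adjusted p = 1.80e-06), and ENSMUST00000117102.3 fell by 1.02 ± 0.06, from 66.9 to 1.49 CPM (adjusted p = 2.20e-06). The 200 transcripts with the smallest p and a positive slope, and the 200 with a negative slope, serve below as the density-rising and density-falling sets. Without LIF the mean level of the rising set minus that of the falling set went from -3.49 (log2 CPM) at 7800 cells per mL to 2.16 at 500000, a range set by how the sets were chosen. DESeq2 called 8961 transcripts on the same slope, and without the 2 libraries at 500000 cells per mL the count was 3401.

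With LIF, which holds the cells in self-renewal, density still moved many transcripts: 3879 rose and 4431 fell. The balance turned with at least 5 CPM (4087 and 3842) and with DESeq2 (5922 and 5825), and was 2373 and 3810 with no filter on low counts. Of the transcripts called in both conditions, 2925 had the same direction, where 592 would be shared by independent lists of these lengths, and 230 had opposite directions. Both lists come from 1 fit, so independence is only a reference point. The density-rising set, chosen on the libraries without LIF, rose with density in those with LIF (camera p = 3.16e-41, and p = 0.00227 with an estimated correlation), with 86.5% of members increasing and a median slope of 0.21 against 0.54 without LIF. The falling set fell (camera p = 5.99e-28, and p = 0.00537 with an estimated correlation), with a median slope of -0.17 against -0.33. Over the 7 libraries with LIF, rising minus falling set level went from 0.04 to 2.11 and followed log2 density with Pearson's r of 0.986 (exact two-sided permutation p = 0.000198) and Spearman's rho of 1 (exact p = 0.000397). Pearson's r was 0.992 in the 5 libraries left without the 2 farthest from the median density. The 4 named transcripts kept a slope of the same sign with LIF except ENSMUST00000028280.13, whose slope of 0.06 ± 0.03 was not called (adjusted p = 0.146).

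**Figure D1:**
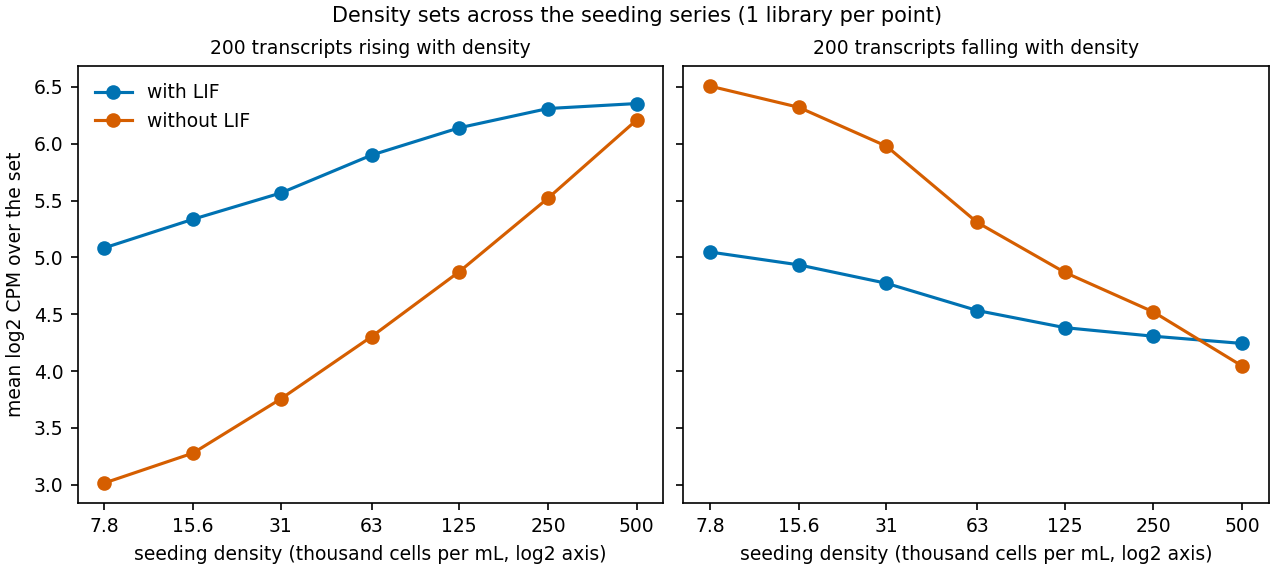
Mean level (log2 CPM) of the 200 density-rising and the 200 density-falling transcripts against seeding density (log2 axis, ticks in 1e3 cells per mL), with 1 library per point, with LIF (blue) and without (orange). The rising minus falling level goes from -3.49 to 2.16 without LIF, where the sets were chosen, and from 0.04 to 2.11 with LIF.

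The density slopes differed between the conditions for 2235 transcripts, with the slope higher without LIF for 1427 and lower for 808 (edgeR's quasi-likelihood test of the difference, adjusted). That balance moved with the filter on low counts, to 1466 and 1303 with at least 5 CPM and to 1153 and 389 with no filter. The number rested on single densities, since leaving out the 2 libraries at the density between 7800 and 31000, or at 31000, 250000 or 500000 cells per mL, gave 973, 1374, 927 and 1341. LIF withdrawal itself, compared within the 7 densities, raised 2922 transcripts and lowered 2609, of which 3367 of 5531 changed by more than 2-fold. Leaving out the libraries at 31000, at 63000 or at the density between 63000 and 250000 cells per mL gave 3431, 3465 and 3586, and DESeq2 called 11417.

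In the knockdown experiment, shCon cells showed the density response in other cultures. The density-rising set was higher at high than at low density (camera adjusted p = 4.41e-48), with a median log2 fold change of 0.78, 94.5% of its 200 members higher, and 55 members called on their own over all transcripts or 134 when adjusted over the list alone. The falling set was lower (adjusted p = 3.18e-38), with a median of -0.41, and 40 of 197 members called, or 97 when adjusted over the list alone. With an estimated correlation the adjusted p of the 2 sets were 0.00324 and 0.00446. Rising minus falling level was -0.28 ± 0.26 (SD, n = 3) at high and -1.80 ± 0.03 (n = 3) at low density. Both sets had been chosen on libraries of the seeding series, so no control was shared. Of the 4 named transcripts, ENSMUST00000087566.10 (log2 fold change 1.85, edgeR adjusted p = 0.0242) and ENSMUST00000117102.3 (-2.30, adjusted p = 8.24e-05) were called here. ENSMUST00000018918.11 (0.42, adjusted p = 0.821) and ENSMUST00000028280.13 (-0.52, adjusted p = 0.202) were not. Over all 41164 transcripts, 370 were higher and 253 lower at high density (edgeR, adjusted). That count depended on the libraries: it was 2199 without high-density shCon replicate 3, 257 and 360 without high-density replicates 2 and 1, and 409, 388 and 301 without low-density replicates 1, 2 and 3. A fit of the 6 shCon libraries alone called 1 transcript, and DESeq2 called 2936.

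The same sets moved with density in the 2 other experiments that had both densities. In the medium exchange controls (2 libraries per density), the rising set was higher at high density (camera adjusted p = 3.72e-48, median log2 fold change 1.28, 96.4% of 196 members higher) and the falling set lower (adjusted p = 5.98e-31, median -0.71), and rising minus falling level was 0.64 ± 0.02 (SD, n = 2) at high against -1.69 ± 0.05 (n = 2) at low density. Of 618 transcripts called in the shCon comparison and tested here, 93.5% had the same sign. edgeR called 18 transcripts higher and 10 lower, a count that was 0 when any 1 of the 4 control libraries was left out (4079 had an unadjusted p under 0.05, and DESeq2 called 2511). With no filter on low counts 749 were higher and 823 lower. In the 3 inducible lines without dox, taken as replicates, the rising set was higher (camera adjusted p = 3.59e-41, median 0.98) and the falling set lower (adjusted p = 6.58e-25, median -0.58) at high density, but neither call held with an estimated correlation (adjusted p = 0.188 and 0.212). In each of the 3 lines the set level was higher at high than at low density, at 0.22 against -1.50 in the β-catenin 4A line, 1.21 against -1.42 in the Yap1 line and -0.96 against -1.71 in the Esrrb line. In all 3 lines the high-density library was replicate 1 and the low-density library replicate 2. Density therefore cannot be separated from replicate number in this comparison. No single transcript was called there by edgeR's quasi-likelihood test after adjustment (2852 of 30830 had an unadjusted p under 0.05, and DESeq2 called 1065). Of the 28 set tests over all contrasts of these 3 experiments, 27 were called with the preset correlation and 19 of those with an estimated one, and the adjusted p of each lost call is given beside it. The 19 held with adjusted p between 0.00103 and 0.0447, far above the preset ones. Estimated correlations reached 0.123 in the knockdown experiment and 0.555 in the lines without dox, against the preset 0.01.

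**Figure D2:**
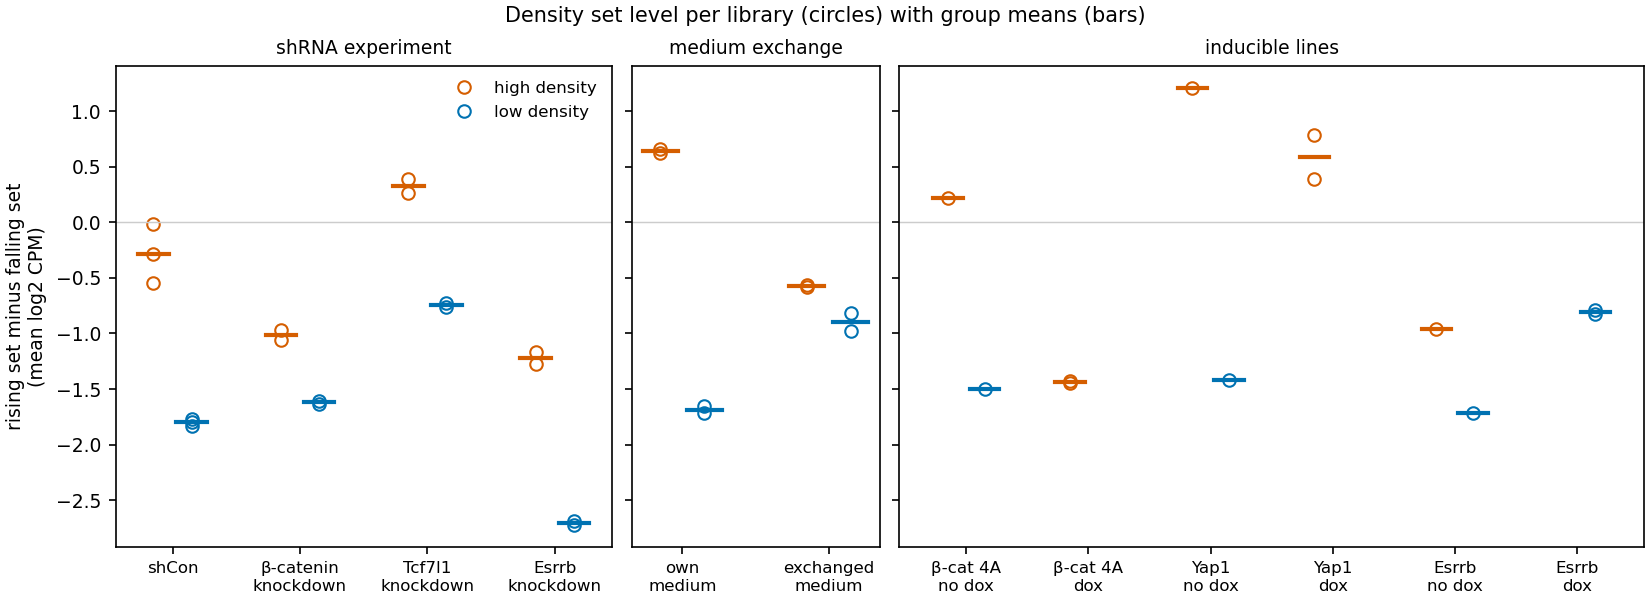
Level of the density-rising minus the density-falling set (mean log2 CPM, vertical axis) in each library (circles) with group means (bars), at high (orange) and low (blue) density. High-density shCon cells average -0.28 and low-density ones -1.80, and exchanging the medium moves high-density cells from 0.64 to -0.57 and low-density cells from -1.69 to -0.90.

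Knockdown of β-catenin in dense cells lowered the transcripts that rise with density. The rising set fell at high density (camera adjusted p = 5.07e-22), with a median log2 fold change of -0.60 and 8.5% of members higher, and rising minus falling level was -1.01 ± 0.06 (SD, n = 2) against -0.28 in shCon. With an estimated correlation the adjusted p of that fall was 0.0160. The falling set was higher with the preset correlation (adjusted p = 9.35e-07, median 0.12) and not with an estimated one (adjusted p = 0.152). In sparse cells β-catenin knockdown lowered the falling set instead (adjusted p = 9.59e-16, or 0.0284 with an estimated correlation, median -0.20). The rising set, with a median of -0.19, was called with the preset correlation (adjusted p = 0.0446) and not with an estimated one (adjusted p = 0.519). Leaving out low-density shCon replicate 1 or 3 or β-catenin knockdown replicate 2 also ended that call (adjusted p = 0.432, 0.0713 and 0.0557), as did shCon replicate 2 or 3 as the lone control (adjusted p = 0.235 and 0.198). Few single transcripts passed: 6 rose and 39 fell at high density, 3 rose and 59 fell at low density (edgeR, adjusted), and 16 were called in the same direction at both densities. DESeq2 called 1075 (358 higher, 717 lower) and 965 (262 higher, 703 lower), a less one-sided balance. At high density edgeR called 294 higher and 540 lower without high-density shCon replicate 3. The high-density count was 834 without high-density shCon replicate 3, 23 without shCon replicate 1, and 137 and 10 without knockdown replicates 1 and 2. The low-density count was 40 and 41 without low-density shCon replicates 1 and 2, and 12 and 15 without knockdown replicates 1 and 2.

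Tcf7l1 knockdown had the opposite sign on the density-rising transcripts. The rising set rose at high density (camera adjusted p = 3.01e-16, median log2 fold change 0.22) and at low density (adjusted p = 2.91e-28, median 0.56, 82.5% of members higher), and the set level was 0.33 ± 0.09 (SD, n = 2) at high and -0.74 ± 0.02 (n = 2) at low density, against -0.28 and -1.80 in shCon. With an estimated correlation the adjusted p of these rises were 0.0284 and 0.0104. With sets chosen in the medium exchange controls instead, the high-density change had the opposite direction and was not called (adjusted p = 0.917). The falling set so chosen was called higher at high density and was not called at low density. The falling set fell at low density with the preset correlation (adjusted p = 1.48e-04, median -0.14) and not with an estimated one (adjusted p = 0.240) or without low-density shCon replicate 1 (adjusted p = 0.0733) or with shCon replicate 3 as the lone control (adjusted p = 0.757). It was not called at high density (adjusted p = 0.635, median -0.07), where its direction reversed without high-density shCon replicate 1 or 3 (adjusted p = 0.759 and 0.635). With a lone control it was called lower against shCon replicate 1 (adjusted p = 0.0197) and higher against replicate 2 (adjusted p = 0.00245). Of single transcripts, 301 were higher and 588 lower at high density, and 451 higher and 460 lower at low density (edgeR, adjusted). At high density the share that was higher also moved, to 776 higher and 841 lower or 1218 and 1360 with shCon replicates 2 or 3 as the lone control, and to 113 and 492 or 97 and 391 without knockdown replicates 1 or 2. The even balance at low density became 191 and 430 without low-density knockdown replicate 1 and 1375 and 773 with shCon replicate 3 as the lone control. Between them, 384 were called in the same direction at both densities and 1 in opposite directions, where 9.87 would be shared by independent lists. Lists from 1 fit are not independent, and a batch difference between knockdown and shCon libraries could also be shared. The high-density count was 488 without knockdown replicate 2, and the low-density count was 324 without knockdown replicate 2 and 421 and 584 without low-density shCon replicates 2 and 3. DESeq2 called 3296 and 3651.

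Esrrb knockdown moved both sets toward the low-density state at low density, and at high density the move of the rising set depended on the control library. The rising set fell at high density (camera adjusted p = 4.95e-13, median log2 fold change -0.31) and at low density (adjusted p = 4.84e-13, median -0.42), and the falling set rose (adjusted p = 1.87e-15 and 3.03e-21, medians 0.25 and 0.22). With an estimated correlation these calls held narrowly, at adjusted p = 0.0447 for the rising set at each density and 0.0308 and 0.0160 for the falling set. With high-density shCon replicate 3 as the lone control, the fall of the rising set at high density was not called (adjusted p = 0.765). Rising minus falling level was -1.22 ± 0.07 (SD, n = 2) at high and -2.70 ± 0.03 (n = 2) at low density. With sets chosen in the medium exchange controls, the low-density changes had the opposite direction and were not called (adjusted p = 0.369 and 0.363). Over all transcripts, 65 rose and 87 fell at high density, and 193 rose and 107 fell at low density (edgeR, adjusted), with 41 called in the same direction at both and 0.531 expected for independent lists. As for Tcf7l1, the lists are not independent and a batch difference could be shared. The high-density count was 647 without high-density shCon replicate 2 and 42 and 37 without knockdown replicates 1 and 2. At low density it was 103 and 161 without shCon replicates 2 and 3, and 114 and 54 without knockdown replicates 1 and 2. The balance of higher and lower was not stable. At low density it turned to 36 higher and 78 lower without knockdown replicate 1 and to 442 and 652 with shCon replicate 1 as the lone control. At high density it turned to 143 and 101 with shCon replicate 2 as the lone control and 1637 and 1508 with replicate 3. DESeq2 called 1950 and 1699.

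The medium exchange asked whether medium conditioned at one density carries part of the density state. After 4 h, dense cells in medium from sparse cells shifted toward the low-density state, and sparse cells in medium from dense cells shifted toward the high-density state. In dense cells the rising set fell (camera adjusted p = 4.71e-21, median log2 fold change -0.60, 13.8% of members higher) and the falling set rose (adjusted p = 8.91e-20, median 0.42). In sparse cells the rising set rose (adjusted p = 6.88e-09, median 0.42, 78.6% of members higher) and the falling set fell (adjusted p = 7.44e-09, median -0.17). All 4 calls held with an estimated correlation (adjusted p between 0.00134 and 0.0244). Exchange brought the set level from 0.64 ± 0.02 (SD, n = 2) to -0.57 ± 0.02 (n = 2) in dense cells and from -1.69 ± 0.05 to -0.90 ± 0.12 (n = 2 each) in sparse cells. No single transcript was called in either exchange by edgeR's quasi-likelihood test after adjustment. In dense cells 2968 of 38368 had an unadjusted p under 0.05 and DESeq2 called 1434. In sparse cells 2443 had an unadjusted p under 0.05, DESeq2 called 886, and edgeR called 258 higher and 796 lower (1054) without replicate 1 of the exchanged low-density cells. These exchanged low-density libraries were the least alike of the 19 replicate pairs (chi-square per degree of freedom of 83.5, r of 0.784).

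The inductions were each compared with a single library of the same line without dox, assumed to vary like the other groups, so a difference of that well or library cannot be separated from induction. Dense cells with dox for β-catenin 4A (125 ng/mL) had 32 transcripts higher and 5 lower than the library without dox (edgeR, adjusted), although the count was 0 without either dox library and 3697 with DESeq2. The falling set was higher with dox (camera adjusted p = 2.35e-25, median log2 fold change 0.56, 86.9% of members higher). The rising set was lower with the preset correlation (adjusted p = 2.10e-18, median -0.69) and not with an estimated one (adjusted p = 0.158), and the set level was -1.43 ± 0.01 (SD, n = 2) with dox against 0.22 in the library without. In dense cells with dox for Yap1 (500 ng/mL) the falling set was higher (adjusted p = 3.64e-09, median 0.17), and the rising set was lower with the preset correlation (adjusted p = 5.82e-10, median -0.30) and not with an estimated one (adjusted p = 0.259). In sparse cells with dox for Esrrb (500 ng/mL) the falling set was lower (adjusted p = 2.39e-15, median -0.19), and the rising set was higher with the preset correlation (adjusted p = 6.31e-27, median 0.48) and not with an estimated one (adjusted p = 0.111). Of the 300 transcripts called after Esrrb knockdown at low density, 20.3% had the same sign in the Esrrb induction. edgeR called no transcript after Yap1 induction (1770 of 36425 with an unadjusted p under 0.05, DESeq2 738) or Esrrb induction (1649 with an unadjusted p under 0.05, DESeq2 704).

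Chromatin occupancy was compared between densities by peak number and overlap, since 2 libraries against 2 cannot give an exact two-sided p below 0.33. Peak coordinates are those of mm10 (GRCm38), and peak fold and q values are the authors'. Esrrb had more peaks in dense cells (13245 and 4207 in replicates 1 and 2, 3958 found in both) than in sparse cells (459 and 2880, 439 found in both). β-catenin had fewer in dense cells (148 and 1516, 52 in both) than in sparse cells (2504 and 2409, 1756 in both). Tcf7l1 peaks were similar in number, with 77178 and 49801 in dense and 70822 and 51151 in sparse cells, and 46162 and 43695 found in both replicates. When the lists of a factor were shortened to the same number of peaks by q value (459 for Esrrb, 148 for β-catenin), 289 and 233 Esrrb peaks and 22 and 97 β-catenin peaks recurred at high and low density.

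**Figure D3:**
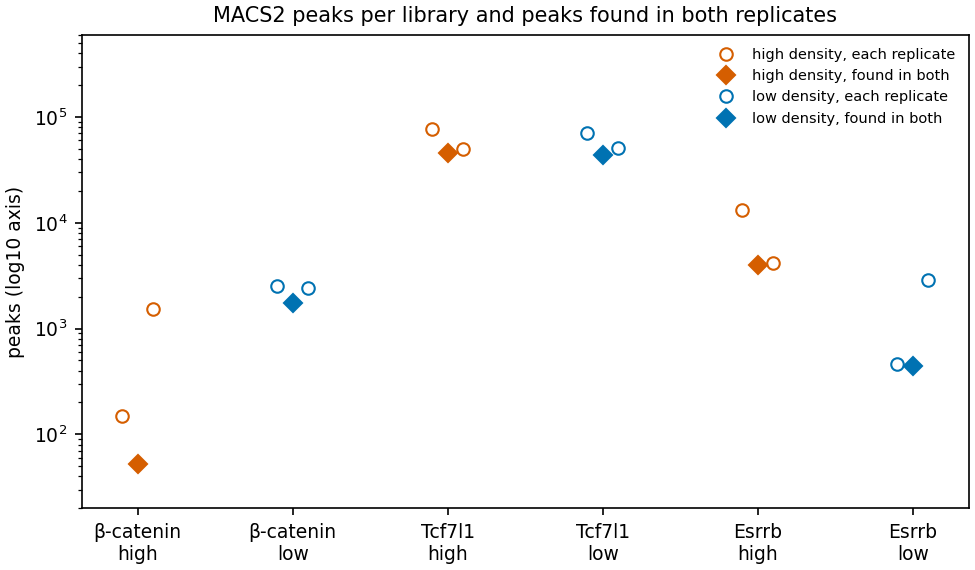
Number of MACS2 peaks (log10 axis) in each replicate (circles) and found in both replicates (diamonds) for β-catenin, Tcf7l1 and Esrrb at high (orange) and low (blue) density. Esrrb peaks found in both replicates number 3958 in dense and 439 in sparse cells, and β-catenin peaks 52 and 1756.

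For Esrrb and β-catenin the smaller set of peaks found in both replicates lay largely inside the larger one by overlap of at least 1 bp. Of the 439 low-density Esrrb peaks, 393 (89.5%) overlapped a high-density one by at least 1 bp, and of the 3958 high-density peaks 390 (9.85%) overlapped a low-density one, against 0.43 after circular shifts of the peaks. Of the 52 high-density β-catenin peaks, 48 (92.3%) overlapped a low-density one, against 0.02 after shifts. For Tcf7l1 the share by overlap of at least 1 bp was lower: 31363 of 43695 low-density peaks (71.8%) overlapped a high-density one. In the other direction 31303 of 46162 high-density peaks (67.8%) overlapped a low-density one. β-catenin peaks coincided with Tcf7l1 peaks: 52 of 52 did at high density and 1715 of 1756 (97.7%) at low density, where shifted peaks gave 20.4. Esrrb peaks overlapped Tcf7l1 peaks for 2801 of 3958 (70.8%) at high and 302 of 439 (68.8%) at low density. The shifts do not keep peaks in accessible chromatin, so they cannot tell these overlaps between factors from shared accessibility. Peaks within 10 kb of a protein-coding gene span made up 64.1% of the Esrrb peaks at high density, 46.6% of the β-catenin peaks at low density and 63.2% of the Tcf7l1 peaks at high density.

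Esrrb peaks lay near naive pluripotency genes, the genes of the ground state that Esrrb belongs to. At high density 11 of 15 members had a peak in both replicates within 10 kb (Esrrb, Nanog, Dppa5a, Fbxo15, Klf2, Nr0b1, Nr5a2, Prdm14, Tbx3, Tfcp2l1 and Zfp42), against 10.8% of 21887 protein-coding genes (two-sided Fisher's exact test, adjusted p = 1.54e-06 over 138 tests). At low density 6 of the 15 did (Esrrb, Dppa5a, Fbxo15, Prdm14, Tbx3 and Tfcp2l1), against 1.32% of genes (adjusted p = 1.54e-06). The 4 with the highest fold in replicate 1 at high density were Prdm14 (chromosome 1, 13127884 to 13128318, beyond the end of its span at 13127163, fold 25.6 and 12.0 in the 2 replicates), Esrrb itself (chromosome 12, 86501523 to 86502350, within its span, 20.3 and 13.7), Dppa5a (chromosome 9, 78369371 to 78369761, 15.7 and 8.33) and Zfp42 (chromosome 8, 43306873 to 43307382, within its span, 14.9 and 8.72). LIF and STAT3 targets also had Esrrb peaks at high density, in 6 of 12 (Gbx2, Icam1, Pim1, Pim3, Sgk1 and Socs3, adjusted p = 0.0172), as did core pluripotency genes at low density, in 3 of 12 (Fgf4, Tdgf1 and Utf1, adjusted p = 0.0125). The other 21 lists were not called at high density (adjusted p of 0.146 or more) nor the other 21 at low density (0.0655 or more). The core pluripotency call was lost at a distance of 50 kb (adjusted p = 0.102), and without replicate 2 the number of lists called at high density was 4 in place of 2.

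β-catenin peaks in sparse cells lay near Wnt targets, in 6 of 16 members (Cdx1, Cdx2, Lef1, Sp5, Tnfrsf19 and Znrf3), and near primitive streak and mesoderm genes, in 6 of 17 (Cdx1, Cdx2, Eomes, Evx1, Nodal and Wnt3), against 3.61% of genes (adjusted p = 5.90e-04 and 6.63e-04). The highest folds among Wnt targets were at Tnfrsf19 (chromosome 14, 61056526 to 61056897, beyond its span, 18.4 and 17.7), Sp5 (chromosome 2, 70474705 to 70475333, overlapping its span, 11.5 and 15.6), Cdx1 (chromosome 18, 61036171 to 61036581, overlapping its span, 10.8 and 15.7) and Lef1 (chromosome 3, 131105841 to 131106305, before its span, 9.27 and 11.1). Among primitive streak genes they were at Wnt3 (chromosome 11, 103770997 to 103771314, before its span, 18.1 and 16.7) and Nodal (chromosome 10, 61415899 to 61416269, before its span, 13.1 and 11.7). YAP and TEAD targets, genes read out by Hippo signalling, had a peak in 4 of 20 (Amotl2, Ccn2, Nt5e and Ptpn14, adjusted p = 0.0428), which did not hold against lists matched on gene span (adjusted p = 0.0947) or at 50 kb (adjusted p = 0.228). Fibroblast markers had a peak in 3 of 10 (Col3a1, Lum and Pdgfrb, adjusted p = 0.0428), of which the Pdgfrb peak was the Cdx1 peak, and were not called at 5 kb (adjusted p = 0.645) or 50 kb (adjusted p = 0.110). At high density none of the 23 lists was called (Fisher's exact test, adjusted p of 0.111 or more). Without replicate 1 that number was 1. The result with both replicates rests on 52 peaks, near 25 protein-coding genes (0.114%), which left little room for a call. Among them, the YAP and TEAD target Nt5e had a peak (chromosome 9, 88332623 to 88332890, within its span, 6.16 and 4.83). Of the Wnt target and primitive streak genes with a sparse-cell peak, replicate 2 alone had dense-cell peaks near Tnfrsf19 (highest fold 5.43), Nodal (5.21) and Wnt3 (4.61). It had none near Cdx1, Cdx2, Lef1, Sp5, Znrf3, Eomes or Evx1.

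**Figure D4:**
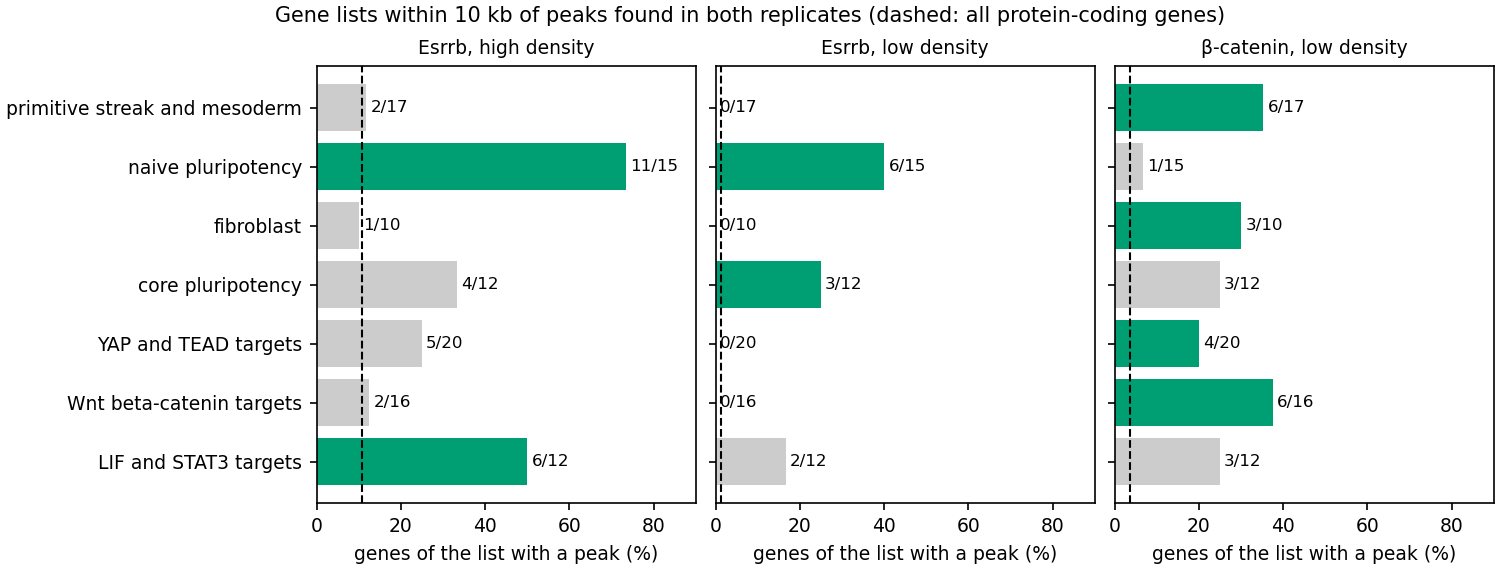
Share of each gene list with a peak within 10 kb (horizontal axis, %), for Esrrb at both densities and β-catenin at low density, with the share of all protein-coding genes dashed and lists called by Fisher's exact test in green. Naive pluripotency genes stand at 11 of 15 and 6 of 15 for Esrrb, and Wnt targets at 6 of 16 for β-catenin.

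Tcf7l1 peaks lay within 10 kb of most protein-coding genes, 69.1% at high and 62.9% at low density, which left little room above that background. All 16 Wnt targets and all 15 naive pluripotency genes had a Tcf7l1 peak at both densities. At high density the lists called were hypoxia and glycolysis (20 of 20), ERK targets and immediate early genes (16 of 16) and Wnt targets (Fisher's exact test, adjusted p = 0.0172, 0.0428 and 0.0428). At low density 6 lists were called, namely Wnt targets, naive pluripotency, YAP and TEAD targets (19 of 20), hypoxia and glycolysis (19 of 20), Nodal and BMP targets (12 of 12) and core pluripotency (12 of 12), with adjusted p between 0.0172 and 0.0428. At 5 kb the hypoxia and glycolysis call was lost at both densities (adjusted p = 0.261 at high and 0.0718 at low) and the ERK target call at high density (adjusted p = 0.0585). Wnt targets were the only list called at high density at both 5 and 10 kb. Against lists matched on gene span, the Wnt target call at high density and the YAP and TEAD call at low density did not hold (adjusted p = 0.0639 and 0.0719). No list was called at either density at a distance of 50 kb. From replicate 1 alone, without replicate 2, 0 lists were called at high density and 1 at low density (Fisher's exact test).

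The pluripotency, Wnt and lineage genes chosen beforehand were occupied as follows. At Nanog (chromosome 6, 122707489 to 122714633), a pluripotency factor, a β-catenin peak of sparse cells overlapped the lower-coordinate end of the gene (122707264 to 122707511, fold 6.47 and 8.57), an Esrrb peak of dense cells covered the same place (122707320 to 122707637, 7.50 and 2.76), and a Tcf7l1 peak of dense cells spanned both (122707061 to 122707657, 10.3 and 7.63). The site was not specific to 1 density, since replicate 2 alone had an Esrrb peak there in sparse cells (122707318 to 122707544, fold 7.88) and a β-catenin peak in dense cells (fold 3.73). Pou5f1 (chromosome 17, 35506032 to 35510777), which encodes Oct4, had a β-catenin peak of sparse cells (35504937 to 35505332, 9.38 and 6.10) and an Esrrb peak of dense cells (35499039 to 35499433, 10.2 and 6.25) before its span. Fgf5, a marker of the primed state, had a β-catenin peak within its span in sparse cells (chromosome 5, 98255786 to 98256022, 7.42 and 7.13). Replicate 2 alone of the other density also had peaks within 10 kb of Pou5f1 (β-catenin fold 3.24, Esrrb 10.4) and of Fgf5 (β-catenin 5.03). Klf4, Sox2, Axin2 and T (Brachyury) had Tcf7l1 peaks at both densities and no β-catenin or Esrrb peak found in both replicates. Each sparse-cell replicate had β-catenin peaks near Axin2 (4 and 1, highest folds 6.73 and 6.07), which did not overlap. Replicate 1 alone had dense-cell Esrrb peaks near Klf4, Sox2, Axin2 and T (highest folds 4.00, 10.2, 6.84 and 8.78). Near T, 1 sparse-cell replicate alone had a β-catenin peak (4.33) and 1 an Esrrb peak (6.54). The highest Tcf7l1 folds were at Sox2 in dense cells (chromosome 3, 34660016 to 34660855, beyond its span, 24.1 and 13.2) and at the Wnt target Axin2 in sparse cells (chromosome 11, 108910450 to 108911282, before its span, 21.9 and 13.5). Of the factor genes themselves, Ctnnb1, Tcf7l1, Esrrb and Yap1 each had Tcf7l1 peaks at both densities, with 7 within 10 kb of Tcf7l1 at either, and Yap1 had an Esrrb peak of dense cells within its span (chromosome 9, 7983680 to 7984067, 13.9 and 10.7), while replicate 2 alone had one within 10 kb of Yap1 in sparse cells (fold 9.65).

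**Figure D5:**
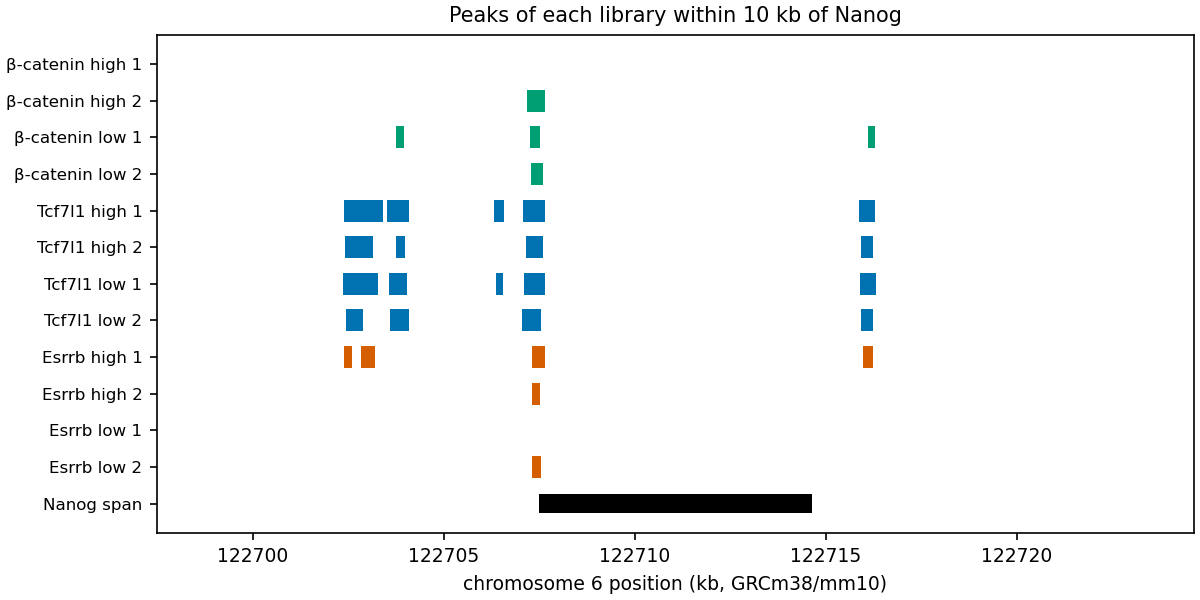
Peaks of each of the 12 libraries (colored bars, named by factor, density and replicate) within 10 kb of Nanog (black bar) on chromosome 6 (position in kb, GRCm38). Peaks of all 3 factors meet at the lower-coordinate end of the gene, including the low-density β-catenin peak at 122707264 to 122707511, and replicate 1 of β-catenin at high density and of Esrrb at low density have none in the region.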

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

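The tests against each lone shCon replicate, the tests of handling and of medium from the other density, the tests of tag depth for Esrrb and β-catenin peaks, and the share of the strongest peaks found again were chosen only after the results were seen. A difference between groups by a direct test drew attention to 5 transcript counts and 6 set tests, and a sample far from the others to 2 values.

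Density slopes with and without LIF differed for 2235 transcripts by the test of the difference (edgeR). Without the 2 libraries at the density between 7800 and 31000, or at 31000, 250000 or 500000 cells per mL, the number was 973, 1374, 927 and 1341. The effect of a knockdown differed between densities for 4 transcripts (β-catenin), 19 (Tcf7l1) and 5 (Esrrb), and that of medium exchange for 7 (edgeR). The knockdown numbers moved with single libraries. For β-catenin they were 7 and 10 without high-density shCon replicates 1 and 3, 1 and 2 without low-density shCon replicates 1 and 2, and 66 and 10 without high-density knockdown replicates 1 and 2. For Tcf7l1 they were 11 without high-density shCon replicate 3, 29 without low-density shCon replicate 1, 110 and 67 without high-density knockdown replicates 1 and 2, and 124 without low-density knockdown replicate 1. For Esrrb they were 62 without high-density shCon replicate 2, 2 without low-density shCon replicate 2, 14 without high-density knockdown replicate 2, and 21 and 2 without low-density knockdown replicates 1 and 2.

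The library at 500000 cells per mL without LIF stood apart from the other 6 in its total (49.2 M counts) and in the share of its counts in its 20 most abundant transcripts (13.7%). Chance marks about 1 in 20 groups in this way. Without the 2 libraries of that density the trend without LIF called 3401 transcripts in place of 5812.

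Medium exchange moved the density sets in opposite directions at the 2 densities, and the tests of that difference gave camera adjusted p = 1.52e-18 for the rising and 6.47e-19 for the falling set (0.0124 and 8.19e-04 with an estimated correlation). Library depth is argued against, since with the 8 libraries thinned to 6.81 M counts the highest of the 4 adjusted p was 5.95e-08 with each direction kept. Handling by the exchange that acts alike at both densities would move the rising set the same way, whereas its medians were -0.60 and 0.42 (the unadjusted p by limma's camera was 5.69e-19 for the difference). That difference is what drew attention to the pattern, and handling that acts differently on dense and sparse cells was not tested. Medium from cells of the other density, the biological explanation that the design names, would move each set toward the density of the medium's source, and all 4 did (the unadjusted p by limma's camera was 1.62e-19 for the falling set), but this is the test that drew attention to the pattern and lends it no further support. It stays open, as does carry-over of cells or RNA with the medium, which was not tested.

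The knockdowns of β-catenin and Tcf7l1 also acted differently on the sets by density, with camera adjusted p = 1.06e-07 (rising) and 1.21e-23 (falling) for β-catenin, and 1.89e-08 and 0.00271 for Tcf7l1, where only the falling set after β-catenin knockdown held with an estimated correlation (adjusted p = 0.0124, others 0.142, 0.135 and 0.406). At high density both libraries of each knockdown correlated best with the same shCon replicate (3 for β-catenin, 1 for Tcf7l1, 2 for Esrrb), the pattern a shared batch would give. The order of the samples in the series places the same pairs side by side at both densities, though no label names a batch. At low density the nearest were 2 for β-catenin and Esrrb and 2 and 1 for the Tcf7l1 libraries, so a library batch shared with 1 replicate was weighed by taking each shCon replicate as the lone control. The highest adjusted p of the rising set was 8.20e-08 for β-catenin at high density, 2.35e-04 and 8.88e-24 for Tcf7l1 at high and low density and 2.36e-08 for Esrrb at low density, each with its direction kept, which argues against such a batch as the whole cause there. It was 0.235 for β-catenin at low density, against the nearest replicate, where a batch and the knockdown cannot be told apart. For Esrrb at high density the call was lost against replicate 3, the farthest control (r 0.805 and 0.813). Against the nearest, replicate 2 (r 0.904 and 0.901), the call held. Rising set levels (mean log2 CPM) were 4.50 and 4.48 in the knockdown libraries, against 5.05, 5.09 and 4.68 in shCon replicates 1, 2 and 3. A batch shared with replicate 2 may exist, but the fall against that replicate argues against it as the cause of the call. The dependence on replicate 3 stays open. The lone-control tests were run with the preset correlation of 0.01 alone, while estimated correlations in this experiment reached 0.123. What they argue against therefore rests on the preset correlation. A biological effect of each knockdown stays open as a hypothesis.

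Peak numbers moved with density in opposite directions for Esrrb (3958 in dense and 439 in sparse cells) and β-catenin (52 and 1756), and this was not tested with 2 libraries each. Depth cannot be told apart from density for Esrrb, where more tags went with more peaks in 3 of the 6 pairs of libraries: the 3 other pairs all hold 1 library, high-density replicate 1 (13.0 M tags, 13245 peaks), and among the remaining libraries those with more tags had more peaks (4207, 2880 and 459). It cannot be told apart for β-catenin either, where the shortest list came from the library with the fewest tags, although among the replicate 2 libraries the low-density one had 1.59 times the peaks (2409 against 1516) from fewer tags (18.9 against 19.6 M). Weaker recovery of the same sites is not decided by the folds. Peaks found at both densities had higher folds than the others, by 1.54 times for Esrrb and 1.95 times for β-catenin. A calling threshold alone would give this. Of the strongest 10% of peaks, 149 of 395 (37.7%, Esrrb, dense cells) and 31 of 175 (17.7%, β-catenin, sparse cells) were found at the other density. The β-catenin share was limited in advance, since 48 peaks were shared at all. Counted the other way, 149 of the 390 shared Esrrb peaks and 31 of the 48 shared β-catenin peaks were among the strongest 10%. A control chromatin library of high density alone and different recovery of the tagged factor were not tested and stay open, as does a change of binding with density.

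Of the 10 splits of the 6 shCon libraries into 3 against 3, the real split called 623 transcripts and the highest other 1150, and of the 10 splits of the lines without dox the real and the highest other called 0 each (edgeR, with 2852 transcripts at an unadjusted p under 0.05 and 1065 by DESeq2 in the real split). The splits are too few in both for a share under 0.05. 2 of the 10 shCon splits called as many as the real one, 10 of 10 did in the lines, and the shCon split that called 1150 points to a structure of the samples other than density. For LIF withdrawal 1 of 50 splits, the real one with 5531 transcripts, called as many, and the highest other called 1. That is the smallest share that 50 splits can give, and the other splits did not keep the pairs of a density. It argues against chance there without excluding it. The splits cannot separate LIF from another difference between the libraries with and without it.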

How the results depend on the processing

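The settings with each shCon replicate as the lone control, the totals without the 20 most abundant transcripts, the fit of the compared groups alone for the set tests, the leave-one-out set tests, and the 5 kb, 50 kb, span-matched and single-replicate settings of the gene lists were chosen only after the results were seen. Of 304 transcript counts under alternatives (21 results), 161 stayed within 1.5 times the reported count and 143 moved further. Of 314 alternative set tests (28 results), 287 kept direction and side of the threshold, 19 lost their call, 1 gained one and 7 reversed. Of 75 alternatives for peaks and gene lists (15 results), 46 stayed and 29 moved. Summed over results and alternatives, reported transcript calls changed sign 67 times, and a transcript can count more than once. Totals without the 20 most abundant transcripts moved no count. RNA gene lists and peaks near density-responsive genes were not run under any setting. In the libraries of 6.81 M counts, 3 counts equal 0.44 CPM. In the medium exchange, edgeR called 0 of 100 simulated transcripts with a log2 change of 2, so the counts of single transcripts there say little. Except where fewer libraries or transcripts were fitted by construction, the cause was not tested.

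DESeq2 called more transcripts: 8961 (trend without LIF, 5812 reported), 4843 (difference of trends), 11417 (LIF withdrawal), 2936 (shCon by density), 1075, 965 and 435 (β-catenin knockdown at high density, at low density and by density), 3296, 3651 and 496 (Tcf7l1), 1950, 1699 and 692 (Esrrb), 2511 (medium controls), 1434 and 886 (exchange at high and low density), 1065 (lines without dox), 3697 (4A), 738 (Yap1) and 704 (Esrrb induction). The split into higher and lower moved by over 10 points for β-catenin knockdown (358 and 717 with DESeq2 against 6 and 39 at high density, 262 and 703 against 3 and 59 at low density), Esrrb knockdown at low density (874 and 825 against 193 and 107) and by density (252 and 440 against 4 and 1, which turned the balance), Tcf7l1 knockdown by density (211 and 285 against 5 and 14), medium controls (1335 and 1176 against 18 and 10) and 4A (2354 and 1343 against 32 and 5). RLE factors gave 58 and counts scaled from TPM 71 for 4A, against 37 reported.

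With no filter on low counts the counts were 3518 (LIF withdrawal), 402 (shCon), 71, 105 and 13 (β-catenin knockdown high, low, by density), 584 and 64 (Tcf7l1 high, by density), 21 (Esrrb by density), 1572 (medium controls), 1070 and 1298 (exchange high, low), 18 (lines without dox), 2305 (4A), 907 (Yap1) and 718 (Esrrb induction). The split of the difference of trends into higher and lower was 1153 and 389 with no filter and 1466 and 1303 with at least 5 CPM, against 1427 and 808. With at least 5 CPM the counts were 1105 (shCon), 72 and 94 (β-catenin high, low), 332, 538 and 22 (Esrrb high, low, by density), 251 (medium controls) and 461 (4A). Fitting only the compared groups gave 1 (shCon), 0, 0 and 1 (β-catenin), 0, 47 and 5 (Tcf7l1), 1, 0 and 1 (Esrrb), 0 (medium controls) and 0 (4A), with fewer libraries by edgeR. The fit of all 12 inducible libraries called 1284 between the lines without dox.

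Whether replicate numbers pair the samples is not settled. With group means removed, shCon libraries of the same number correlated at 0.192, 0.0187 and 0.213 between densities. Those of different numbers correlated at -0.225 to 0.100. Knockdown libraries of the same number correlated between densities at -0.0425 (β-catenin), -0.0553 (Tcf7l1) and 0.0556 (Esrrb). With the replicate block the counts were 1082 (shCon), 427 and 629 (β-catenin knockdown high, low), 0 (medium controls) and 0 (4A), and the block changed no other count by over 1.5 times and no set call.

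With shCon replicates 1, 2 and 3 as the lone control, the counts were 1093, 1834 and 258 (β-catenin high), 2477, 424 and 187 (low) and 191, 225 and 156 (by density), 582, 244 and 3145 (Esrrb high), 1094, 677 and 880 (low) and 402, 182 and 912 (by density). For Tcf7l1 they were 903, 1617 and 2578 (high), 996, 1460 and 2148 (low) and 18, 141 and 470 (by density), so the order of the 3 knockdowns by count changed with the control. The sets lost or changed their call as follows (adjusted p): β-catenin low rising 0.235 and 0.198 with replicates 2 and 3, Tcf7l1 low falling 0.757 with replicate 3, Esrrb high rising 0.765 with replicate 3, and Tcf7l1 high falling called at 0.0197 with replicate 1 and in the other direction at 0.00245 with replicate 2.

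With an estimated correlation, calls were lost for β-catenin high falling (adjusted p = 0.152), β-catenin low rising (0.519), Tcf7l1 low falling (0.240), lines without dox rising and falling (0.188 and 0.212), 4A rising (0.158), Yap1 rising (0.259) and Esrrb induction rising (0.111), all by camera. β-catenin low rising was 0.0581 with 100 and 0.0625 with 400 transcripts per direction. With sets from the medium controls, Tcf7l1 low falling was 0.866, and directions reversed for Tcf7l1 high rising (0.917) and falling (0.0358) and Esrrb low rising (0.369) and falling (0.363).

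Leaving out 1 library, or the 2 of a density, gave these ranges: 3401 to 5363 (trend without LIF), 5788 to 7932 (with LIF), 927 to 1982 (difference), 3431 to 6112 (LIF withdrawal), 257 to 2199 (shCon), 10 to 834, 12 to 79 and 1 to 66 (β-catenin knockdown high, low, by density), 488 to 1075, 324 to 1316 and 11 to 124 (Tcf7l1), 37 to 647, 54 to 417 and 2 to 62 (Esrrb), 0 to 0 (medium controls), 0 to 1054 (exchange low) and 0 to 0 (4A), by edgeR. Set tests ranged from adjusted p 0.0107 to 0.432 (β-catenin low rising), 0.0699 to 0.759 (Tcf7l1 high falling, reversed without high-density shCon replicate 3 at 0.635 and replicate 1 at 0.759) and 8.99e-07 to 0.0733 (Tcf7l1 low falling).

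Peaks of 1 replicate alone, in place of both, ranged from 148 to 1516 (β-catenin high), 49801 to 77178 and 51151 to 70822 (Tcf7l1 high, low), and 4207 to 13245 and 459 to 2880 (Esrrb high, low), and those shared between densities from 95 to 320 (β-catenin), 33415 to 54777 (Tcf7l1) and 435 to 1952 (Esrrb). Lists of the same number of peaks gave 22 and 97 (β-catenin high, low), 289 and 233 (Esrrb high, low), and 11 and 122 shared peaks (β-catenin, Esrrb). A -log10 q of at least 5 gave 30 β-catenin high peaks, 29 of them shared. Reciprocal overlap of 50% of each peak gave 42 β-catenin high peaks, 24 of them shared. For Esrrb it gave 3552 high and 395 low peaks, with 202 high peaks shared. Gene lists called were 7 at 5 kb, 0 at 50 kb and 5 with span-matched draws for Tcf7l1 high (3 reported, of which 5 kb kept Wnt targets and lost hypoxia and glycolysis at adjusted p = 0.261 and ERK targets at 0.0585, and 1 of the 7 was a depletion, two-cell-like genes at 0 of 8, Fisher's exact adjusted p = 0.00567), 2 at 50 kb for β-catenin low (4 reported) and 0 at 50 kb for Tcf7l1 low (6 reported), and from 1 replicate 0 to 1 (β-catenin high), 0 to 3 (Tcf7l1 high), 1 to 4 (Tcf7l1 low) and 2 to 4 (Esrrb high).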

Other observations

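The peaks named in this paragraph were chosen after their values were seen, and the overlap test before. At low density 32 of 1756 β-catenin peaks (1.82%) overlapped an Esrrb peak, against a mean of 0.14 after circular shifts, and at high density 8 of 52 (15.4%) did, against 0.06. These shifts cannot tell such overlap from shared accessible chromatin. The strongest Esrrb peaks of dense cells, by the lower fold of the 2 replicates, lay at Map2k1 (chromosome 9, 64198933 to 64199449, fold 31.8 and 21.7), which encodes the ERK kinase MEK1, and at Ski (chromosome 4, 155163164 to 155163734, 32.5 and 20.4), a corepressor of TGF-β signalling. The strongest β-catenin peak of sparse cells had no protein-coding gene within 10 kb (chromosome X, 161053866 to 161054289, 26.6 and 27.3), and another lay at Ppp4r4 (chromosome 12, 103564262 to 103565097, 24.0 and 25.7). Tcf7l1 in sparse cells reached 45.4 and 36.9 at Rreb1 (chromosome 13, 37801703 to 37803030).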
